A study of Mus musculus with 4 samples.

How the data were processed

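Whole-genome bisulfite sequencing libraries were made by post-bisulfite adaptor tagging (PBAT), in which adaptors are added after bisulfite treatment, from germ cells of 21-day-old mouse testes. Per the labels' protocols, seminiferous tubules were picked by hand, dissociated and passed through a 95 µm mesh to remove interstitial cells, and 2 µg of genomic DNA was converted with bisulfite. The samples were 2 controls carrying a floxed Np95 gene (Np95fl/fl) and 2 knockouts that also carried Stra8-Cre, a recombinase expressed in premeiotic male germ cells. Np95, also named Uhrf1, recruits the maintenance methyltransferase Dnmt1 to newly replicated DNA. Nothing in the labels says whether the samples of a group came from separate animals, so p-values measure spread between these samples, which may be technical. For most regions that spread is shared between regions of the same kind and is not the region's own.

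The deposited table gives, in percent, the share of reads methylated at each cytosine of a CpG in each sample, with the cytosines of both strands listed separately and no value where a sample had none. Per the submitters' processing notes the genome build was mm10. The aligner and the methylation caller are not given in the sources used here. The title of the deposited table names a minimum of 10 reads. On chromosome 19, 4.56% of the 2668142 values strictly between 0 and 100 were multiples of 1/7, against 7.56% for 1/11 and 7.20% for 1/13. The read depth of each value is unknown, so no confidence interval for single cytosines was computed and every value had the same weight. The table lists 37230584 cytosines in 19267362 CpGs on chromosomes 1 to 19 and X, and the listed X positions end at 60490732. Of the listed cytosines, 29774194 and 29509008 had a value in control replicates 1 and 2, and 28999710 and 29530971 in knockout replicates 1 and 2. All analyses used the 22421484 cytosines (60.2%) with a value in all 4 samples unless stated. On the X chromosome 9.91% of listed cytosines met this condition. No pair of sample columns was identical.

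Gene positions came from a table for assembly GRCm38.p6, which is the same build as mm10. It gives the start and end of each gene without the strand. The planned promoter window was therefore replaced by a CpG-rich gene end. It runs from 1000 bp outside to 500 bp inside the gene end that lists at least 2 times as many CpGs as the other end, with at least 5 CpGs measured. Such an end may not be the promoter of every gene. Gene bodies were trimmed by 2000 bp at both ends. No genome sequence was used here, so CpG islands were taken as runs of at least 30 listed CpGs per 500 bp, and flanking bases of CpGs and repeats were not analysed. Windows of 10 kb, gene bodies and islands needed at least 10 CpGs measured. Windows for paternally methylated imprinted regions lay at fixed distances upstream of H19, Meg3, Rasgrf1 and Zdbf2, with the strand of these 4 genes taken from general knowledge. Of 181 symbols in the fixed gene lists, 4 were not in the gene table.

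The methylation level of a region was the mean over its cytosines. Differences are knockout minus control, in percentage points, and a retained share is the knockout mean over the control mean, in percent. Regions were tested with limma 3.58.1 (R 4.3.3), with a trended prior variance and robust estimation, on log2((m + 0.01)/(1 − m + 0.01)) of the level m as a fraction. For 99.0% of windows and 98.9% of gene bodies the prior had no finite degrees of freedom, so their p-values rest on a variance pooled over regions with the same mean level. For gene ends and islands the prior had 7.87 and 6.76 degrees of freedom (medians), against 2 from the region itself. An alternative added after seeing the data tested each region on its own spread alone. Changes on this scale are understated for levels near 0 and near 1. A region was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. Gene lists were tested with limma's camera at a preset correlation of 0.01. Single values per sample were compared with an exact two-sided permutation test, which for 2 against 2 samples cannot give a p below 0.333. Where an analysis left 1 sample in a group, that sample was assumed to vary like the other group. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9 and the R package data.table (version 1.17.8) were also used.

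The region test was tested on simulated data with losses planted in 50 regions per size. Over 233810 windows it recovered 100% of losses of 40 and 30 points, 84% of 20 points and 10% of 10 points. Over 13022 gene ends it recovered 92%, 72%, 12% and 2% of the same sizes, over 15776 gene bodies 98%, 100%, 100% and 34%, and over 16151 islands 100%, 92%, 58% and 6%. Regions without a planted change gave 9 calls among windows, 0 among gene ends, 6 among gene bodies and 1 among islands. In this simulation small losses at gene ends and islands were mostly missed. It planted losses only, at control levels of at least 50%, and no gains. Nearly all regions were left unchanged, which makes the adjusted p stricter than in the real data. Losses of 10 points also lay at the minimum difference of a call. Of 746 ends at 20% to 80% in controls, with a median difference of -19.7 points, 554 were called lower. The recovery rates thus do not give the power of the test on the real data.

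The genes named were set by a rule written before the data were examined. It takes the 10 protein-coding gene ends with the largest called loss and the 10 with the largest called gain, with both knockouts on the same side of both controls, 5 gene bodies and 3 windows per direction by the same rule, called members and examples of 11 fixed gene lists, and Uhrf1. Symbols that are Gm with digits or end in Rik were left out of the ranked genes. CpG islands were named after their values were seen. Alternatives covered the scale and offset, thresholds, numbers of CpGs, window definitions, centring on each sample's median, a term for the replicate number, and each sample left out in turn. Those that need read depth or a genome sequence were not run.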

Results

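DNA methylation was measured across the genome in male germ cells of 21-day-old mice, in 2 control samples with an intact floxed Np95 gene and 2 knockout samples in which Stra8-Cre deletes it. Np95 (Uhrf1) maintains CpG methylation through DNA replication, and the stated question was how much methylation germ cells lose without it. The number of cytosines with a value was similar, between 28999710 and 29774194 per sample, and the reads behind each value are unknown. Coordinates are mm10.

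Methylation of the genome was lower in both knockout samples than in both controls. Over the 22421484 cytosines measured in all samples, the mean level was 71.0% ± 2.68 (SD, n = 2) in controls and 38.2% ± 0.236 (SD, n = 2) in knockouts. The values were 69.1% and 72.9% in the controls and 38.1% and 38.4% in the knockouts. The difference was -32.7 points, many times the SD within either group, and the knockouts retained 53.9% of the control level. The exact two-sided permutation test gave p = 0.333, the smallest value that 2 against 2 samples allow.

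The loss came with a shift of most cytosines to intermediate levels. In controls 63.2% ± 6.63 (SD, n = 2) of cytosines were methylated at 80% or more, against 2.18% ± 0.0603 (SD, n = 2) in knockouts. The share between 20% and 80% was 19.2% ± 6.52 in controls and 74.8% ± 0.0140 in knockouts. The share at 20% or less was 17.7% ± 0.111 in controls and 23.0% ± 0.0463 in knockouts. Cytosines listed at exactly 0 made up 11.2% and 11.1% of the total. Cytosines with a mean control level of at least 80% averaged 91.4% in controls and 48.3% in knockouts, so 52.8% was retained. Those with a mean control level under 20% averaged 3.47% ± 0.0297 in controls and 4.88% ± 0.644 in knockouts. Both classes were set on the same control values that are reported, so part of each change may come from the selection.

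**Figure D1:**
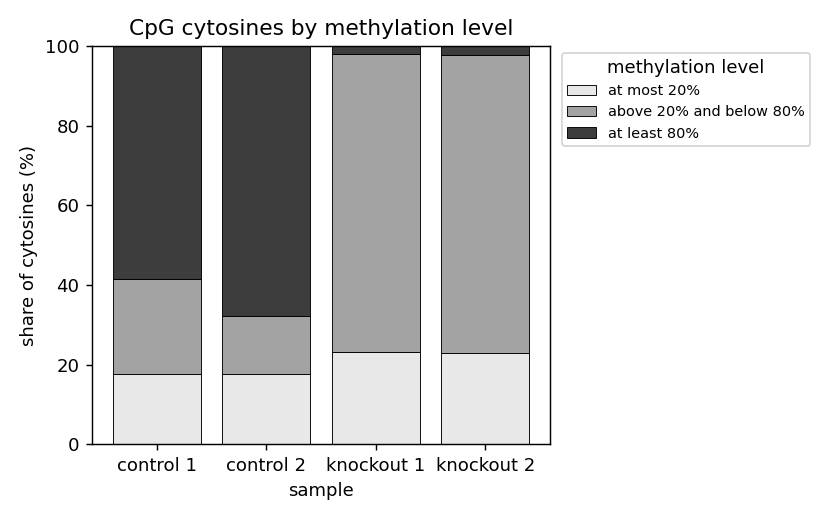
Share of CpG cytosines (y axis, percent) at 3 ranges of methylation level in each of the 4 samples (x axis), over the 22421484 cytosines measured in all samples. The darkest part, cytosines at 80% or more, falls from a mean of 63.2% in controls to 2.18% in knockouts, and the middle part grows from 19.2% to 74.8%.

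The loss was nearly uniform across autosomes. Chromosome 13 retained the smallest share, 53.4%, and chromosome 17 the largest among autosomes, 54.3%. The X chromosome had a mean of 56.6% ± 1.77 (SD, n = 2) in controls and 33.8% ± 0.0710 (SD, n = 2) in knockouts, a retained share of 59.7%. The gap between X and autosomes was -14.4 points in controls and -4.48 points in knockouts, a difference of 9.94 points (exact permutation p = 0.333). It rests on 42175 X cytosines in the first 60490732 bp, and with each sample on its own cytosines, an alternative added after seeing the data, it was 6.63 points. Part of the difference came with the lower control level of X, since an equal retained share would also narrow the gap. The retained share was 59.7% on X against 53.9% on autosomes.

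Isolated CpGs lost more methylation than CpGs with close neighbours. CpGs with no other listed CpG within 35 bp averaged 81.6% ± 3.56 (SD, n = 2) in controls and 42.4% ± 0.392 (SD, n = 2) in knockouts, a retained share of 52.0%. CpGs with 3 or more neighbours averaged 36.1% ± 0.801 in controls and 21.8% ± 0.0707 in knockouts, a retained share of 60.5%. The contrast between isolated and dense CpGs was 45.5 points in controls and 20.6 points in knockouts, a difference of -24.9 points (exact permutation p = 0.333). Most of this difference came with the lower control level of dense CpGs. Among cytosines with a mean control level of at least 80%, a class set on the same control values, it was -4.45 points. In this class isolated CpGs retained 51.4% and dense CpGs 57.0%. With neighbours counted within 100 bp, the difference over all cytosines was -13.9 points.

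**Figure D2:**
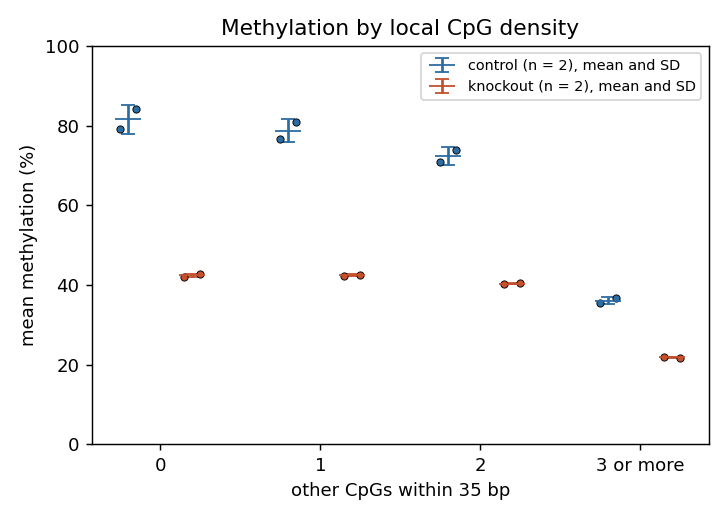
Mean methylation (y axis, percent) of CpGs grouped by the number of other listed CpGs within 35 bp (x axis), with a point per sample and bars for the mean and SD of each group (n = 2). Isolated CpGs go from 81.6% in controls to 42.4% in knockouts, and CpGs with 3 or more neighbours from 36.1% to 21.8%.

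Most windows across the genome lost methylation. Of 233810 windows of 10 kb, limma called 226814 (97.0%) lower and 2 higher in knockouts, and the median window went from 85.3% to 43.5%. The largest losses were on chromosome 4 at 15010001 to 15020000 in Necab1, which fell by 58.4 points, on chromosome 10 at 46420001 to 46430000 outside annotated genes, which fell by 57.4 points, and on chromosome 10 at 64760001 to 64770000 in Ctnna3, a gene for an alpha catenin, which fell by 57.0 points. The 2 gains were on chromosome 9 at 123920001 to 123930000, from 14.9% ± 1.35 to 37.9% ± 0.147 (SD, n = 2 each), and on the X chromosome at 57400001 to 57410000, from 20.4% ± 1.91 to 30.8% ± 7.21. The X window was not called without control replicate 2 (9.07 points) or without knockout replicate 1 (5.33 points), and 2 to 10 windows were called higher with 1 sample left out. With no minimum difference 84 windows of 10 kb were called higher, and of 493179 windows of 1 kb 420616 were called lower and 1635 higher. These tests rest on a variance pooled over windows. With each window's own spread in limma, an alternative added after seeing the data, 221647 windows were called lower and 1 higher, and the X window was lost (adjusted p = 0.168). With each sample centred on its own median on the log2 scale of the test, 3784 windows were called lower and 75935 higher. On this scale an equal retained share gives a smaller change at a lower control level. These calls therefore do not show which windows retained more or less than the typical share.

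Gene bodies behaved like the windows. Of 15776 protein-coding gene bodies, limma called 15289 lower and 2 higher, and the median gene body went from 86.9% to 46.0%. The largest losses were in Snorc, which fell by 55.7 points from 90.5% ± 2.43 (SD, n = 2), Fbxo39, which fell by 52.8 points, Tmem247, which fell by 52.8 points, Gstm1, a glutathione transferase gene, which fell by 52.7 points, and Colca2, which fell by 52.6 points. The gains were in Magel2, an imprinted gene of the Prader-Willi region, from 7.14% ± 1.31 to 19.2% ± 4.51, and in Ctrb1, which encodes chymotrypsinogen, from 12.4% ± 3.52 to 22.5% ± 5.11 (SD, n = 2 per group). These tests too rest on a pooled variance. With each gene body's own spread in limma (added after seeing the data), 15149 were called lower and 1 higher, Magel2 was near the threshold (adjusted p = 0.0485) and Ctrb1 was lost (adjusted p = 0.146). Neither gain held when each sample was left out in turn, since Magel2 was at 8.84 points without knockout replicate 1, and Ctrb1 at 6.50 points without knockout replicate 2 and 7.63 points without control replicate 2. Centred on the sample medians, 75 gene bodies were called lower and 4420 higher, with the same limit from the scale of the test as for windows.

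CpG-rich gene ends, which are rich only by comparison with the other end of the gene, were mostly unmethylated and stayed so. Those methylated in controls lost methylation, and many of them hold few CpGs, such as Csn3 with 6 measured. Among ends with at least 30 CpGs listed (added after seeing the data), 211 of 11143 were called lower and 19 higher. Of all 13022 ends, 1502 were called lower and 33 higher. All of these calls need the variance shared between ends: with each end's own spread in limma, which leaves 2 degrees of freedom (added after seeing the data), 0 were called, and C1qtnf7 had an adjusted p of 0.165. All 941 ends with a control level of at least 80% were called lower, with medians of 89.3% in controls and 46.2% in knockouts. Of the 11335 ends under 20% in controls, 7 were called lower and 33 higher, and their median level was 1.71% in controls and 1.59% in knockouts. The largest losses were at C1qtnf7, which fell by 60.2 points from 85.3% ± 8.37 (SD, n = 2; adjusted p = 0.000654 by limma), Csn3, which encodes kappa-casein and fell by 59.1 points, Il5ra, the interleukin 5 receptor alpha gene, which fell by 58.7 points, and Spaca3, a gene for a sperm acrosome protein, which fell by 57.5 points. Pramel15, Casp4, Tafa1, Ccr2, Col6a1 and B3galt2 followed, with losses from 57.2 to 55.9 points. At Csn3 the knockout samples differed, 16.2% and 43.5%.

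The gains at gene ends were smaller than the losses. Rhox3f on the X chromosome (37580352 to 37581852), a reproductive homeobox gene, went from 2.54% ± 0.980 to 25.6% ± 16.0 (SD, n = 2 each, adjusted p = 0.0186 by limma). Its knockout samples differed, 14.3% and 37.0%, and its gain was 34.4 points without knockout replicate 1 and 11.8 points without knockout replicate 2. Rhox2h went from 14.2% ± 0.175 to 31.5% ± 5.33, Naa11, which encodes an N-terminal acetyltransferase, from 6.51% ± 1.41 to 22.7% ± 0.880, and Jade1 from 4.97% ± 0.360 to 20.4% ± 6.33. Prps1l1, Cmtm2b, Cd200r1, Mael, Ccdc152 and Ppp1r14bl gained between 12.0 and 14.5 points. Without knockout replicate 1 the calls of Prps1l1 (7.22 points), Cmtm2b (9.05 points), Cd200r1 (9.74 points), Mael (adjusted p = 0.439 by limma), Ccdc152 (6.38 points) and Ppp1r14bl (9.97 points) were lost, and that of Rhox3f was lost without control replicate 1 (adjusted p = 0.0504 by limma). On untransformed fractions the calls of Rhox3f (adjusted p = 0.146), Prps1l1 (0.0660) and Ccdc152 (0.0529) by limma were lost too. Without control replicate 2 the calls of Prps1l1 and Ccdc152 were lost at adjusted p = 0.122 and 0.128 by limma. The number of ends called higher was 11 without knockout replicate 1 and 82 without knockout replicate 2, and 10 with the window extended to 2000 bp outside the gene. The end of Uhrf1 itself (chromosome 17, 56302337 to 56303837) was at 10.9% ± 0.460 in controls and 4.63% ± 1.05 in knockouts (difference -6.30 points, adjusted p = 0.00231), under the 10 points required. Methylation of this end does not show whether the gene was deleted, so it does not check the labels.

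CpG islands showed the same split. Of 16151 islands, 940 were called lower and 50 higher, and with each island's own spread in limma (added after seeing the data) 0 were called. Of 686 islands with a control level of at least 80%, 680 were called lower, with medians of 86.9% in controls and 58.8% in knockouts. All 50 gains lay among the 15046 islands under 20% in controls. The largest gain, chosen after its values were seen, was on chromosome 9 at 123924361 to 123925849, in the long non-coding RNA gene Gm51701. It went from 5.17% ± 0.0979 to 48.2% ± 0.932 (SD, n = 2 each; adjusted p = 0.000131, and 0.147 with its own spread) over 94 CpGs. Also chosen after their values were seen, islands at Jade1 went from 4.19% ± 2.56 to 24.9% ± 4.86 and at Ankrd31, a gene needed for meiotic DNA breaks, from 2.26% ± 0.471 to 18.0% ± 1.21 (SD, n = 2 each). The island at Stra8, the retinoic acid target that starts meiosis, was at 3.83% ± 2.67 in controls and 18.9% ± 8.48 in knockouts (24.9% and 12.9%). Only the knockouts carried Stra8-Cre, so reads from any Stra8 sequence in the transgene cannot be told from reads of the native island. The call of the Stra8 island was fragile. It was lost on untransformed fractions (adjusted p = 0.0716 by limma) and without control replicate 2 (0.204), knockout replicate 1 (0.256) or knockout replicate 2 (0.0617), and that of Jade1 was lost without knockout replicate 1 (0.0883). Without knockout replicate 1, 540 islands were called, of which 7 were higher, and without knockout replicate 2, 617 were called lower. Without control replicates 1 and 2, 31 and 17 islands were called higher.

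**Figure D3:**
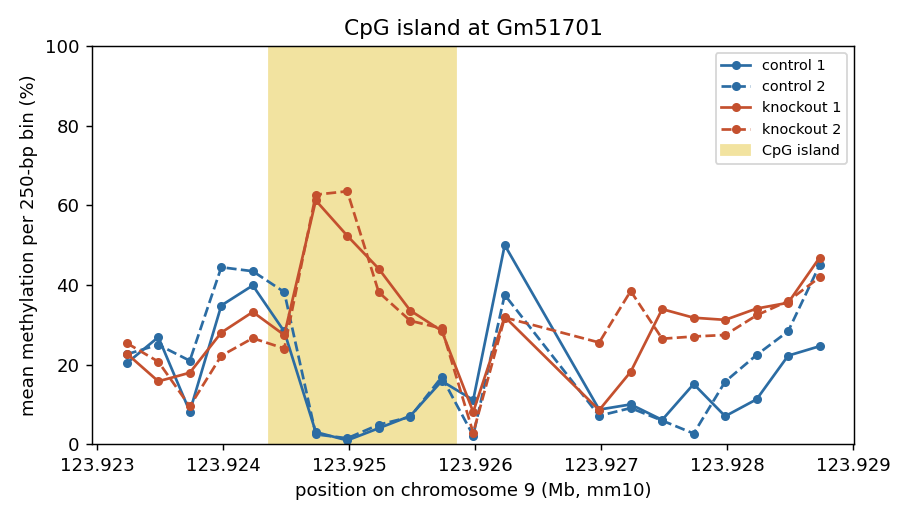
Mean methylation per 250-bp bin (y axis, percent) along chromosome 9 around the CpG island at Gm51701 (x axis, position in Mb), with a line per sample and the island shaded. Over the island both knockouts average 47.5% and 48.8% and both controls 5.10% and 5.24%.

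The 2 sets of imprinted regions differed in region type and control level, so no effect of parental origin can be read from them. H19, Meg3, Rasgrf1 and Zdbf2 were chosen for a region methylated on the paternal copy. In windows upstream of them, controls had a mean of 84.9% ± 3.79 (SD, n = 2) and knockouts 42.7% ± 3.83 (SD, n = 2), a difference of -42.2 points (exact permutation p = 0.333). The windows lay 1500 to 5000 bp upstream of H19, 5000 to 20000 bp upstream of Meg3 and Zdbf2, and 20000 to 40000 bp upstream of Rasgrf1. They may hold much sequence outside the imprinted regions. The median 10-kb window of the genome went from 85.3% to 43.5%, so these values show no loss particular to imprinted regions. H19 went from 89.3% ± 3.68 to 44.5% ± 7.55 and Rasgrf1 from 72.5% ± 5.58 to 34.2% ± 3.22. The 15 ends of maternally methylated imprinted genes had a mean of 11.6% ± 0.257 in controls and 10.6% ± 1.44 in knockouts, a difference of -1.04 points that was smaller than the SD between knockouts (exact permutation p = 0.667). With each sample left out in turn, the difference ranged from -2.06 points (without knockout replicate 1) to -0.0158 points (without knockout replicate 2). Of these ends 10 were higher in knockouts, with both samples above both controls at 7 and below both at 3; all ends share the same 4 samples, so these counts are not independent. Peg10 went from 2.22% ± 1.23 to 7.48% ± 5.06 and Nnat from 3.96% ± 1.66 to 10.8% ± 4.64, neither past the threshold. Snrpn, at 65.3% in controls, and Fkbp6, at 29.5%, were called lower and fell by 31.9 and 14.9 points. They retained 51.1% and 49.4%, against 50.2% in the windows of paternally methylated regions. The Snrpn end held only 5 measured CpGs, and either end may lie outside the imprinted region of its gene. Their losses therefore do not show a loss at a maternally methylated region. The call of Fkbp6 was lost without control replicate 2 (adjusted p = 0.225) or without knockout replicate 1 (adjusted p = 0.107). The sign of the mean turned with 500 bp on each side of the gene end (1.47 points over 14 ends, Snrpn not among them) and for the difference between the medians over regions of each sample (2.91 points).

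Gene lists fixed before the data were examined were compared at CpG-rich ends. Ends of germline genes that are methylated in somatic tissues were higher in knockouts. Of 17 tested, 16 had a positive difference and 4 were called higher (5 adjusted over the list alone), and the mean went from 7.85% to 15.0%. The sample means were 8.48% and 7.21% in controls and 17.2% and 12.8% in knockouts. Mael, a piRNA pathway gene, went from 4.10% ± 3.42 to 16.6% ± 2.49 (SD, n = 2 each), Dazl, an RNA-binding regulator of germ cells, from 5.94% ± 2.71 to 17.4% ± 5.19, and the synaptonemal complex genes Sycp3 from 6.41% ± 2.77 to 17.1% ± 0.315 and Sycp1 from 4.65% ± 0.637 to 14.7% ± 3.99. Leaving out 1 sample ended each of these 4 calls: Mael without knockout replicate 1 or 2 (adjusted p = 0.439 and 0.488 by limma), Dazl without knockout replicate 1 (7.82 points) or control replicate 2 (9.57 points), Sycp1 without the same samples (7.26 and 9.63 points), and Sycp3 without control replicate 1 (8.78 points). Camera put the list above other ends (adjusted p = 4.95e-12), but not with an estimated correlation (adjusted p = 0.273 with an estimated correlation). Beside this list, the 13 ends of maternally methylated imprinted genes under 20% in controls, a set chosen after seeing the data, went from 6.13% ± 0.909 to 8.53% ± 1.76.

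The meiotic list, which shares Hormad1, Syce1, Sycp1 and Sycp3 with the germline list, had 28 ends tested, 18 with a positive difference, 2 called higher (Sycp1 and Sycp3) and 1 called lower. The lower one was Spata22, a meiotic recombination gene, which fell by 43.3 points from 81.9%. Of 14 piRNA pathway ends, Mael was called higher and Piwil2, which encodes a piRNA-binding protein, lower by -31.2 points from 72.6%; adjusted over the list alone, 2 were higher and 1 lower. Camera put the meiotic (adjusted p = 5.21e-06), piRNA (adjusted p = 0.000378) and maternally methylated imprinted lists (adjusted p = 0.00119) above other ends, and these calls were also lost, at adjusted p = 0.273, 0.273 and 0.528 with an estimated correlation. The mean difference of the imprinted list and the median of the differences at its ends had opposite signs, -1.04 and 1.88 points.

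**Figure D4:**
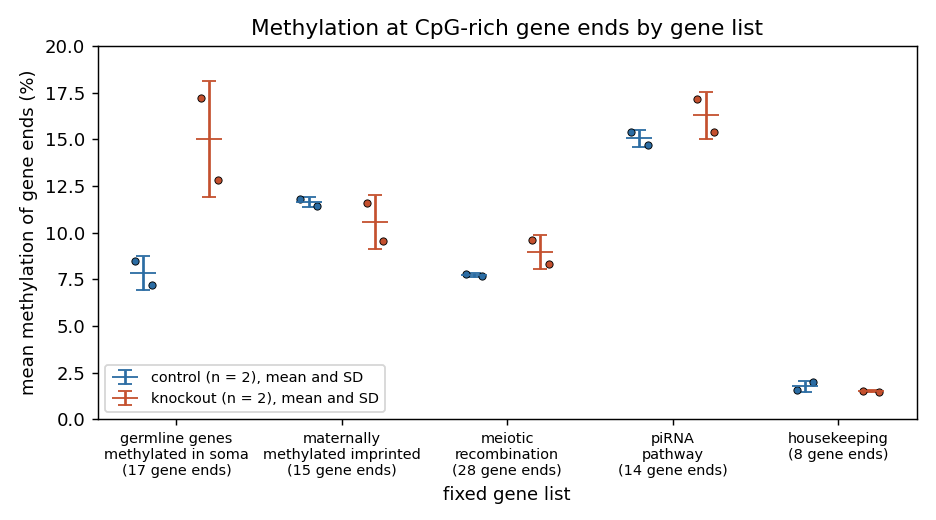
Mean methylation of CpG-rich gene ends (y axis, percent) in 5 fixed gene lists (x axis), with a point per sample and bars for the mean and SD of each group (n = 2). Germline genes methylated in soma go from 7.85% to 15.0%, while housekeeping ends stay at 1.77% and 1.51%.

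The other lists did not pass the list test. Among 10 ends of DNA methylation and demethylation genes (adjusted p = 0.592), Dnmt1, the maintenance methyltransferase gene, was called lower, from 91.9% ± 1.93 to 53.2% ± 1.83 (SD, n = 2 each), at an end that may not be its promoter. Among 10 spermatogonial ends (adjusted p = 0.465) none was called; Sohlh2, a transcription factor gene of early spermatogonia, was at 7.12% ± 1.35 and 16.5% ± 1.80, and Sohlh1, its partner, at 8.08% ± 0.118 and 16.2% ± 3.70. Sohlh2 and Sohlh1 passed without knockout replicate 2 (10.7 and 10.8 points), and Sohlh2 also without control replicate 1 (10.4 points) and with centring (10.3 points). Among 5 ends of late spermatocyte and spermatid genes (adjusted p = 0.488), Acrv1, an acrosomal protein gene, was called lower by -45.8 points, and Pou5f2 was at 13.5% and 16.7%. None of 9 Sertoli cell marker ends was called (adjusted p = 0.746); Fshr, the follicle-stimulating hormone receptor gene, was at 26.8% ± 0.287 and 17.3% ± 1.31, and Inha at 13.6% ± 2.06 and 5.42% ± 0.927. Fshr passed without knockout replicate 1, at -10.4 points. Of 5 Leydig, peritubular, vessel and immune marker ends (adjusted p = 0.528), Hsd3b1, a steroid synthesis gene, was called lower, from 94.3% ± 0.702 to 48.8% ± 0.808, and Lhcgr was at 16.8% and 11.6%. The 3 tested ends of paternally methylated imprinted genes (adjusted p = 0.108) held no call; Zdbf2 was at 4.75% ± 0.514 and 12.8% ± 6.12 and Meg3 at 10.5% and 11.7%. Without knockout replicate 2 this list passed (adjusted p = 0.00667 by camera in limma) and so did Zdbf2 (12.4 points), and with an estimated correlation the list had adjusted p = 0.579 by limma. The 8 housekeeping ends had a mean of 1.77% in controls and 1.51% in knockouts with no call (adjusted p = 0.582), among them Ppia at 3.10% and 1.85% and B2m at 3.14% and 2.40%. Camera's direction was opposite to the mean for the Sertoli, housekeeping and late spermatocyte lists, and opposite to the median for the Sertoli, housekeeping and spermatogonial lists.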

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

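Alternatives were planned before the data were examined, except those named here as added. Among the values that answer a comparison, 82 stayed, 23 moved and 3 reversed. Differences stayed if they moved by no more than the larger SD within a group, and counts if they lay within a fixed ratio of the main count. With 2 samples per group, leaving 1 out cannot move a difference between group means past that SD. A replicate block leaves such a difference unchanged. These differences therefore stayed by construction, which is no sign that they are robust. The genome-wide difference was -46.4 points as a median over cytosines and -35.8 over 10-kb windows, which give each window the same weight. The density contrast was -13.9 points within 100 bp, -8.53 points as a difference of retained shares in percent, and -4.45 points for cytosines at 80% or more in controls (added). The X contrast was 13.3 points as a median, 12.7 over windows and 6.63 on each sample's own cytosines (added). The maternally methylated ends reversed to 1.47 points with 500 bp on each side, where Snrpn drops out, 2.91 as a difference between per-sample medians and 2.41 for ends under 20% in controls (added). Centring left 79719 windows and 4495 gene bodies called; of 493179 windows of 1 kb 422251 were called, 1635 of them higher, and of 24470 windows of 100 kb 24415 were called, 0 higher. Gene ends called numbered 3070 with no minimum difference, 2361 with 2000 bp outside, 5184 with no ratio between ends (added) and 230 with at least 30 CpGs listed (added). Islands called numbered 547 at 25 points and 13801 at 20 CpGs per 500 bp (added). With each region's own spread in place of a shared prior variance (added), 221648 windows, 15150 gene bodies, 0 gene ends and 0 islands were called, with 2 degrees of freedom left. Leaving out each sample gave 540 to 922 islands. No list passed with an estimated correlation (0 of 11) or with fry (0), a self-contained test; the smallest adjusted p by fry was 0.0505. Directions of lists not called turned for DNA methylation (0.816 with 500 bp), spermatogonial (0.624 by fry), late spermatocyte (0.624 by fry), Sertoli (0.112 by fry and 0.816 with 500 bp), Leydig (0.864 with 500 bp) and housekeeping ends (0.568 by fry), as adjusted p. With each sample left out, the Meg3 end ranged from -0.836 to 3.11 points (-0.0792 without control replicate 2) and Pou5f2 from -2.35 to 8.69 points. Of single regions, lists and counts per direction, 626 values stayed, 94 lost their call, 7 gained one, 10 changed direction and 47 counts moved. Where no construction is named, the cause was not tested. Deviations of same-numbered samples correlated at 0.0527 over windows, which does not show whether these samples share an origin. At germline gene ends replicate 1 lay above replicate 2 in both groups (8.48% and 7.21% in controls, 17.2% and 12.8% in knockouts). With a replicate block 226832 windows, 1552 gene ends, 15292 gene bodies and 1063 islands were called, 90 of the islands higher. Weighting by depth, other depth limits, the GC-based island definition and repeats were not run, since neither depth nor sequence was used here. Unknown depth limits the precision of single cytosines and short regions.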

Other observations

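All tests in this part were chosen after the results were seen. The share of methylation retained in gene bodies differed between gene families, grouped by symbol after the values were seen. Over 12224 gene bodies with at least 20 CpGs and a control level of at least 70%, the mean retained share was 55.2% ± 3.70 (SD over gene bodies). Zinc finger genes (Zfp, 269 gene bodies) retained 57.4%, at 57.2% and 57.7% in the knockouts. Keratin genes (Krt, 27) retained 51.3%, collagen genes (Col, 34) 51.9%, serpin genes (37) 52.5%, potassium channel genes (Kcn, 53) 52.9%, cytochrome P450 genes (57) 53.2% and solute carrier genes (314) 54.0%. In a permutation test that rotated the family labels along the genome, so that neighbouring genes stayed together, these 7 of 10 families had adjusted p from 0.000205 to 0.000584, and from 0.000205 to 0.00199 against gene bodies of the same CpG density. Olfactory receptor genes (15) retained 53.1% (adjusted p = 0.0362, and 0.0925 at the same density), vomeronasal type 2 receptor genes (38) 54.5% (adjusted p = 0.287) and tripartite motif genes (47) 55.2% (adjusted p = 0.938).

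The retained share was read over 22711 windows of 100 kb with at least 100 CpGs and a control level of at least 50%. It correlated between the knockouts at 0.806 when each was divided by a different control, though windows are not independent replicates. Among those with a control level of at least 70%, the lowest shares were 40.5% and 43.2% in neighbouring windows on chromosome 7 from 47900001 to 48100000. These hold the sensory receptor genes Mrgpra4 and Mrgprx1. The highest was 67.4% on chromosome 10 at 83400001 to 83500000, at Aldh1l2. Among islands under 20% in controls, 12 of the 50 gained islands (24.0%) had an annotated pseudogene within 1000 bp, against 361 of 14996 others (2.41%; Fisher's exact test, two-sided, p = 2.35e-09).

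The gain at ends of germline genes may reflect a higher share of somatic cells in the knockout preparations, where these ends are methylated. Genes of the maternally methylated imprinted list were chosen for a region methylated in somatic cells and not in male germ cells. The gene end used may lie outside that region, and the Grb10 end was at 1.10% in controls and 1.12% in knockouts. Of the 13 ends of this list under 20% in controls, 10 were higher in knockouts. They gained a mean of 2.41 points over the 13 ends, against 7.16 points at the germline ends. Both sets gained more in knockout replicate 1 (3.66 and 9.38 points) than in replicate 2 (1.16 and 4.95 points). The full imprinted list, whose members methylated in controls fell, had a mean difference of -1.04 points, and the preparation used a mesh against interstitial cells. Incomplete bisulfite conversion would have raised housekeeping ends, which differed by -0.258 points. New methylation in the knockout germ cells stays open: the germline gain exceeded 2 times the imprinted gain by 2.35 points (standard error 0.708 between samples), but 3 times that gain by -0.0602 points (SD 1.83 in controls and 2.16 in knockouts), and how far the imprinted ends are methylated in somatic cells was not measured here, so it cannot be told apart from a somatic share.

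Knockout samples retained a median of 53.5% of the control level over the 22711 windows of 100 kb, with 1st and 99th percentiles of 48.9% and 63.4%. A mixture of cells methylated like the controls and fully unmethylated cells predicts 1 share for all CpGs. However, CpGs with 3 or more neighbours retained at least 4.99 points more than isolated CpGs. This held in both knockouts and with the controls split between selection and denominator. These values bear on that mixture only, since mixtures that hold cells with another methylation profile were not tested. A single halving in every cell is 1 candidate explanation, with a kept share that varies between sites. It needs shares of at least 50% in the germ cells. The shares here are those of the whole preparation. Somatic cells in it that kept their methylation would raise them, so a share of 50% or more does not exclude a larger loss in germ cells. Of the 22711 windows of 100 kb, 4.77% lay under 50%. A further limit of 2 SD of replicate noise under 50% was passed by 0.286%, among them the 2 on chromosome 7 at 40.5% and 43.2%. The 1% of regions with the lowest share in 1 knockout and 1 control retained in the other samples, over control replicate 2, 48.4% and 48.9% for windows of 100 kb, 47.7% and 47.7% for windows of 10 kb and 46.5% and 47.3% for gene bodies, but over control replicate 1 51.0% and 51.4%, from 50% up to 50.4%, and 49.1% and 50.3%. The side of 50% thus mostly turned on the control used, so for these regions a single halving and a larger loss cannot be told apart, although the window in Necab1 picked for its loss went from 85.9% to 27.5%, and cell mixtures with different numbers of replications were not modelled.

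The island at Gm51701 stood apart from the other gains. A gain of 43.0 points from somatic cells alone would need a somatic share at least that much higher in knockouts. The largest gain at a germline end of the fixed list was 12.5 points, at Mael, and the Rhox3f end gained 23.1 points. These values argue against somatic cells as the only source, but do not exclude them, since somatic methylation was not measured here. Methylated copies of the sequence read in all samples would have raised the controls, which were at 5.17%. The island lies beside 50409 bp without listed CpGs, and a copy or variant linked to the knockout animals may account for it: the lower knockout lay 42.3 points above the higher control, and the design holds no other animals to separate such a variant from the genotype, so the 2 cannot be told apart.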
